A study of Mus musculus with 6 samples.

How the data were processed

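The data were expression values from 6 Affymetrix mouse gene arrays, each hybridised with total RNA of an iPSC culture, 3 naive and 3 primed by the labels. The deposited values are log2 values made with RMA (robust multi-array average) in Partek 6.6, per the submitters' processing notes. Options for background correction, normalization and summary are not given in the sources used here, nor is a genome build. Array medians over 35556 probe sets lay between 7.77 and 7.83. Medians over the genes tested were 8.28 to 8.29 on naive and 8.35 to 8.38 on primed arrays. RMA compresses differences of dim genes, and the table carries no detection calls. Background was therefore set on each array as the 95th percentile of 1194 olfactory and vomeronasal receptor genes, which lay between 6.96 and 7.02. A group was taken to be in background where each of its 3 arrays lay under its own cutoff.

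Probe sets were named through GEO's platform annotation, in which 21789 had 1 gene symbol, 1621 had several and 12146 are not named here. Of the first kind, 21698 matched the RefSeq table of assembly GRCm38.p6 by gene ID, which gave current symbols, chromosomes and gene order. Probe sets with several symbols were not used. For each gene the probe set with the highest mean over all arrays was taken, which left 19938 genes. Of 999 genes with several probe sets, 11 had probe sets past the threshold in opposite directions.

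Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, without covariates, on the deposited values without further normalization), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The labels call the arrays biological replicates without saying what was repeated, so the p-values measure the spread between these cultures. There were 27 gene lists with 432 genes, of which 393 were measured. Of these, 26 lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, and the sex-linked list was read gene by gene. Chromosomes were tested with camera and an estimated correlation on genes above the median mean expression.

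Samples, lists, tests, alternatives and the rule for named genes were set before the data were examined, except where a choice is said to be later. The rule took the 12 genes with the largest difference in each direction among those past the threshold whose groups did not overlap (leaving out predicted genes, small RNA genes and receptor genes), a set of pluripotency and sex-linked genes, and the 4 members of each list with the largest difference. Other members and genes are named to describe a list and were picked after their values were seen.

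Runs of neighbouring genes were sought on 9954 expressed genes with a scan of normal scores in gene order (runs of at least 10 genes, 1000 permutations; Python 3.11.15, numpy 2.4.6). On simulated data the scan recovered 93 of 100 genes planted with a shift of 0.5. In simulated arrays with the real spread of 19938 genes, the gene test recovered 24% of genes changed by 0.25, 86% of those changed by 0.5 and 100% of those changed by 1 or 2, with 5 unchanged genes called. There camera called the planted list and 0 of 25 others. The simulated genes varied independently, while estimated correlations within the real lists lay between -0.04 and 0.52. The simulation therefore does not show how camera with the preset correlation behaves on correlated genes. Alternatives were other scalings, a filter at the 40th percentile of mean expression, the mean over probe sets, an intensity trend, array weights, the replicate number as a block, stricter thresholds, other list tests and leaving out each array. No array was left out of the comparison.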

Results

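Total RNA from mouse induced pluripotent stem cells (iPSCs, cells reprogrammed from fibroblasts) was measured on 6 arrays, 3 from cells kept in naive culture and 3 from cells kept in primed culture. Naive medium held 15% fetal bovine serum and leukaemia inhibitory factor (LIF) at 1000 U/ml, and primed medium was conditioned by embryonic fibroblasts and held basic FGF at 8 ng/ml. The titles call the arrays of each group biological replicates. They give embryonic fibroblasts as the origin of the naive cells and adult dermal fibroblasts as that of the primed cells. Another label gives embryonic fibroblasts for all 6. By the titles culture state and origin of the line changed together, and by the other label the origin was shared; the labels do not settle which holds. The study set its lines beside naive and primed cells from the literature; the comparison made here is between its own groups. All differences are primed minus naive on the log2 RMA scale, so that a negative value is a higher level in naive cells. Their precision is limited by the 3 arrays per group. The labels do not say what was repeated, so the p-values may not cover differences between lines kept in the same state.

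The primed and naive iPSCs measured here differed in a large part of the measured transcriptome. Slc38a4, an imprinted amino acid transporter gene, showed the largest difference, from 12.29 ± 0.04 in naive cells to 6.16 ± 0.12 in primed cells (SD, n = 3), a log2 difference of -6.13 (SE 0.06, limma adjusted p = 4.9e-13). Grb10, an imprinted gene for an adaptor that restrains growth factor signalling, went the other way, from 7.99 ± 0.05 to 12.67 ± 0.04 (SD, n = 3), a log2 difference of 4.68 (SE 0.05, adjusted p = 5.9e-13). Penk, which encodes an opioid peptide precursor, was higher in primed cells by 4.44, with a naive mean of 7.06 near background. Gatm, for the enzyme that starts creatine synthesis, rose by 3.81. Dppa2, a gene of early embryos and pluripotent cells, was higher in naive cells by either of its probe sets (-3.72 in the brighter and -2.68 in the other).

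Among 19938 genes, 4347 were higher in primed and 4529 higher in naive cells at an adjusted p under 0.05. Most of these differences were small, with a median size of 0.36. Only 340 and 367 genes respectively passed the threshold and differed at least 2-fold. The other genes with the largest rise in primed cells were Fv1 (3.44), Gstm5 (3.43), Kdm5d (3.25), Rarb (3.15), Tdrkh (3.08), BC107364 (3.03), AI506816 (3.01), Esrrb (2.98) and Chac1 (2.95). Rarb encodes a retinoic acid receptor, Tdrkh a protein of the piRNA pathway and Chac1 an enzyme that degrades glutathione. On the naive side they were Nlrp9b (-4.58), Akr1c18 (-4.52), AU015836 (-4.06), Trim25 (-3.56), Irgm1 (-3.42), S100a6 (-3.39), Dnmt3l (-3.19), Lix1 (-2.94), Peg10 (-2.94) and Ifitm1 (-2.92). Trim25, Irgm1 and Ifitm1 are interferon-responsive genes, and Dnmt3l encodes a cofactor of the de novo DNA methyltransferases. Replicate arrays correlated across genes at r of 0.998 to 0.999, against 0.980 between groups. The values of the groups did not overlap for 52.9% of genes, where chance gives 10%. Values of Slc38a4, Nlrp9b, Akr1c18, AU015836, Trim25 and Dnmt3l in primed cells, and of Gatm, Gstm5, Kdm5d and BC107364 in naive cells, lay within the background of olfactory and vomeronasal receptor genes. Differences of these genes are compressed on that side. The means of Lix1 in primed cells (6.98) and of AI506816 in naive cells (7.02) were near background.

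**Figure D1:**
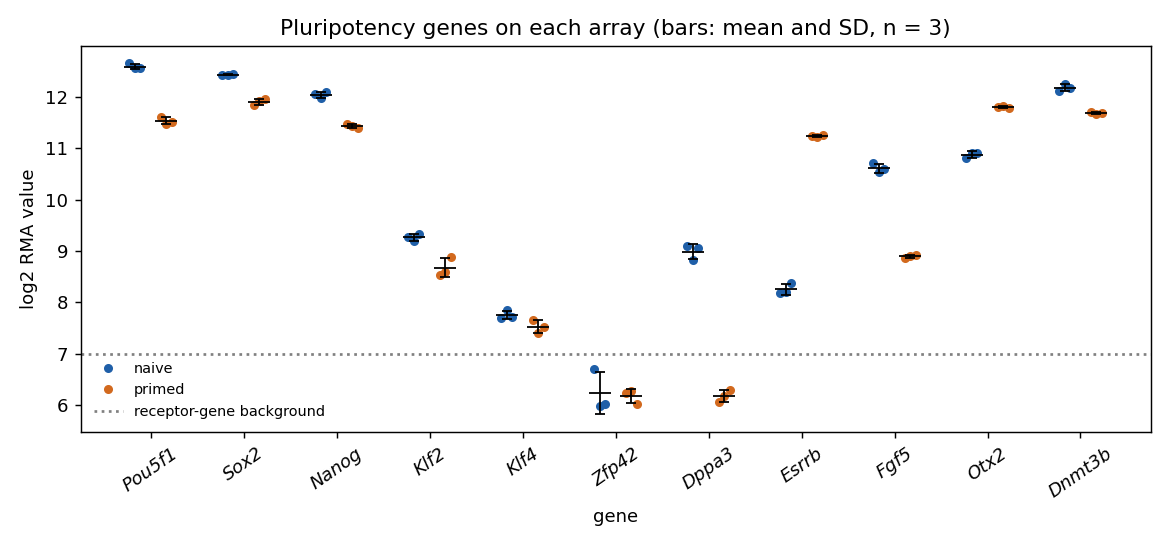
Log2 RMA value of 11 pluripotency genes on each of the 3 naive (blue) and 3 primed (orange) arrays, with black bars for the mean and SD and a dotted line for the mean receptor-gene background. Dppa3 fell to background in primed cells, Esrrb rose by 2.98, and Zfp42 lay in background in both groups.

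Pluripotency genes of the naive state were split between the groups. In the list of naive-state factors, 14 of 24 measured genes were higher in naive cells, 6 were higher in primed cells and 4 did not pass; adjusted over the list alone, the counts were 14 and 7. Dppa2 (-3.72, or -2.68 in another probe set), Dppa3 (-2.81, in background in primed cells), Klf2 (-0.59) and Nanog (-0.61) were among the first group. Esrrb rose from 8.25 ± 0.11 to 11.24 ± 0.02 (SD, n = 3) and Nr0b1 rose by 2.29. Both are factors that sustain self-renewal in naive cells. Klf4 was lower in primed cells by a small margin (-0.23, adjusted p = 0.019). This call ended without naive replicate 2 (adjusted p = 0.080) or without primed replicate 2 (adjusted p = 0.087). Zfp42 was at 6.24 ± 0.41 and 6.18 ± 0.14 (SD, n = 3), inside the background in both groups. The list as a whole was higher in naive cells with the preset correlation (camera adjusted p = 0.024), against an adjusted p = 0.34 with an estimated correlation.

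Core pluripotency genes, which both states express, were lower in primed cells in 10 of 14 cases, higher in 2 and past the threshold in neither direction in 2, with the same counts adjusted over the list alone. Pou5f1 went from 12.59 ± 0.05 to 11.53 ± 0.07 (SD, n = 3), a difference of -1.06. Zfp296 differed by -1.04, L1td1 by -0.96, Gdf3 by -0.84 and Sox2 by -0.52, while Sall1 rose by 0.73. The list test gave an adjusted p of 0.0038, and an adjusted p = 0.29 with an estimated correlation. Genes of the primed, post-implantation epiblast state divided almost evenly, with 10 of 24 higher in primed cells, 9 higher in naive cells and 5 not passing, again with the same counts adjusted over the list alone (adjusted p = 0.74). Otx2, a transcription factor of the post-implantation epiblast, rose by 0.92 and Car14, a carbonic anhydrase gene, by 2.11. Fgf5, a widely used marker of that state, went from 10.61 ± 0.09 to 8.90 ± 0.03 (SD, n = 3), a difference of -1.71. Lef1 (-1.38), Krt18 (-1.33) and Dnmt3b (-0.50) were also lower in primed cells. The list gene T was not analysed here.

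Targets and components of LIF and STAT3 signalling, the pathway fed by the naive medium, were lower in primed cells in 14 of 18 cases. In 1 case the gene was higher and 3 did not pass, with the same counts adjusted over the list alone. Lifr, the LIF receptor gene, differed by -1.86, Bcl3 by -1.05, Socs3, a feedback inhibitor of the pathway, by -0.88 and Myc by -0.67. Another Socs3 probe set did not pass (-0.12, adjusted p = 0.064). This list had an adjusted p of 9.2e-05, and an adjusted p = 0.30 with an estimated correlation. Targets of FGF and ERK signalling, the pathway fed by basic FGF in primed medium, were higher in naive cells in 10 of 18 cases and in primed cells in 4, with 4 not passing and the same counts adjusted over the list alone (adjusted p = 0.023, and adjusted p = 0.46 with an estimated correlation). Spry4 (-1.48), Phlda1 (-0.97), Etv5 (-0.91) and Dusp5 (-0.91) were lower in primed cells, and Dusp6, a phosphatase of ERK, rose by 0.48.

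In the Nodal and Activin list, 9 of 15 genes were higher in naive cells, 1 in primed cells and 5 did not pass, the same adjusted over the list alone. The adjusted p was 0.0054, and adjusted p = 0.36 with an estimated correlation. Lefty2, an inhibitor and target of Nodal that was in background in primed cells, differed by -1.72, Fst by -1.08 and the Nodal co-receptor gene Tdgf1 by -0.80. Wnt targets were higher in naive cells in 8 of 15 cases and in primed cells in 3, with 4 not passing, or 10 and 3 adjusted over the list alone (adjusted p = 0.024, and adjusted p = 0.29 with an estimated correlation). Wnt3 (-1.79), Lef1 (-1.38) and Sp5 (-1.12) were lower in primed cells and Rnf43, which removes Wnt receptors, rose by 0.86.

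Neuroectoderm genes were higher in primed cells in 11 of 19 cases and in naive cells in 0, with 8 not passing. Adjusted over the list alone, the counts were 12 and 1. Pax6, a transcription factor of the early neural plate and eye, rose from 6.56 ± 0.10, in background, to 8.85 ± 0.20 (SD, n = 3), and Sox21 rose by 0.88, Fabp7 by 0.87 and Map2 by 0.82. The list had an adjusted p of 0.00094, and an adjusted p = 0.18 with an estimated correlation. Trophoblast genes were higher in naive cells in 10 of 14 cases and in primed cells in 0, with 4 not passing, or 11 and 0 adjusted over the list alone. Krt7 (-1.92), Gata3 (-1.28), Plac1 (-1.01) and Ascl2 (-0.97) led this group (adjusted p = 9.2e-05, and adjusted p = 0.18 with an estimated correlation).

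Markers of fibroblasts, the cells of origin and of feeder layers, were higher in naive cells in 12 of 23 cases and in primed cells in 3, with 8 not passing, or 13 and 4 adjusted over the list alone (adjusted p = 0.024, and adjusted p = 0.29 with an estimated correlation). In this list 6 of the 23 genes lay in background in both groups. The contractile genes Acta2 (-1.23) and Tagln (-1.09) and the collagen gene Col1a1 (-0.76) were lower in primed cells, but the matrix proteoglycan gene Dcn rose by 2.89. Epithelial genes were higher in naive cells in 10 of 16 cases and in primed cells in 3, with 3 not passing and the same counts adjusted over the list alone (adjusted p = 0.024, and adjusted p = 0.46 with an estimated correlation). The keratin genes Krt8 (-1.73) and Krt18 (-1.33) fell in primed cells and the tight junction genes Cldn3 (1.39) and Ocln (1.29) rose.

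Imprinted genes moved mostly toward naive cells, with 11 of 15 higher in naive cells, 3 in primed cells and 1 not passing, the same adjusted over the list alone (adjusted p = 0.0097, and adjusted p = 0.29 with an estimated correlation). Grb10 was the largest rise, while Peg10 (-2.94), Rian (-1.61) and Dlk1 (-1.59) were lower in primed cells. Dlk1, Rian, Meg3 and Rtl1, all lower in primed cells, belong to 1 cluster on chromosome 12, and 11 of the 15 genes lie outside it. The count and the list test therefore do not rest on 15 independent genes. Antigen presentation and interferon genes were higher in naive cells in 5 of 12 cases and in primed cells in 2, with 5 not passing and the same counts adjusted over the list alone (adjusted p = 0.021, and adjusted p = 0.41 with an estimated correlation). Ifitm1 (-2.92, or -3.58 in another probe set), Ifitm3 (-2.55), Irf1 (-1.94) and Tapbp (-1.27) led the list. Another Irf1 probe set showed no difference past the threshold (0.00, adjusted p = 0.98). Stress-response genes were higher in primed cells in 8 of 13 cases and in naive cells in 2. The other 3 did not pass, and the counts were 9 and 2 adjusted over the list alone. Chac1 (2.95), Trib3 (1.51), Ddit3 (1.46) and Herpud1 (1.35), which respond to unfolded proteins or lack of amino acids, rose in primed cells (adjusted p = 0.0043, and adjusted p = 0.29 with an estimated correlation).

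**Figure D2:**
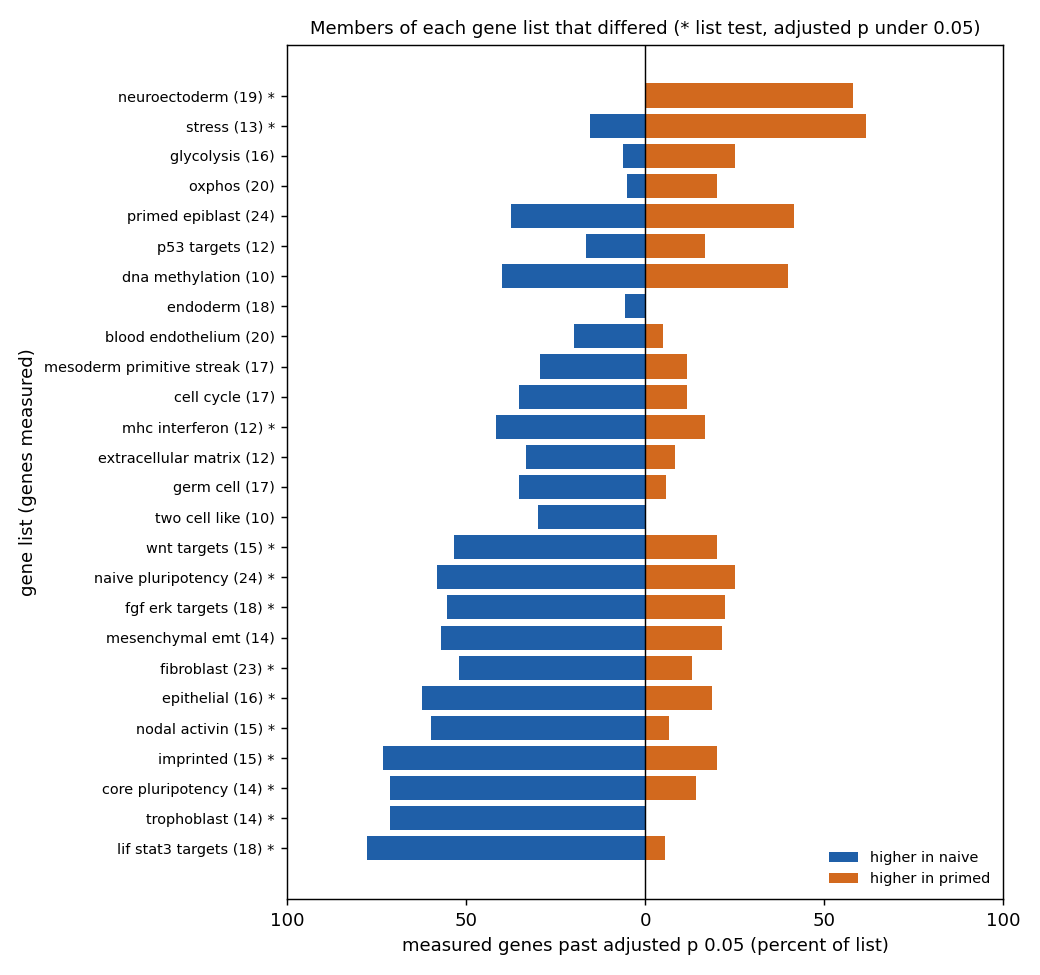
Percent of the measured genes in each of 26 lists that were higher in naive (blue, left) or primed (orange, right) cells at an adjusted p under 0.05, with the number of genes measured in parentheses and a star where the list test with preset correlation passed. The LIF and STAT3 list reaches furthest to the left with 14 of 18 genes, and neuroectoderm genes lie wholly to the right.

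The remaining lists did not pass the list test. Genes that set, maintain, protect or remove DNA methylation went both ways, 4 up and 4 down of 10 with 2 not passing (adjusted p = 0.81). Examples are Dnmt3l (-3.19), Tet2 (0.95), Dnmt3a (0.82) and Tet3 (0.60). Germ cell genes were higher in naive cells in 6 of 17 cases and in primed cells in 1, with 10 not passing (adjusted p = 0.15). Of the 17, 11 lay in background in both groups, where a gene that did not pass cannot be read as unchanged. Tdrkh rose by 3.08, and Dppa3 (-2.81), Prdm1 (-1.71) and Sycp3 (-1.67) were lower in primed cells, Dppa3 and Sycp3 being in background there. Mesoderm and primitive streak genes were higher in naive cells in 5 of 17 cases and in primed cells in 2, with 10 not passing (adjusted p = 0.12). They were led by Eomes (-2.20) and Wnt3 (-1.79), with Fgf8 at -0.60 and Hand1 at -0.60. Blood and endothelial genes were higher in naive cells in 4 of 20 cases and in primed cells in 1, with 15 not passing (adjusted p = 0.12). The largest differences were those of Tek (-1.42), Runx1 (-0.93) and Gata2 (-0.71), and 5 of the 20 genes lay in background in both groups. Mesenchymal transition genes were higher in naive cells in 8 of 14 cases and in primed cells in 3, with 3 not passing (adjusted p = 0.15). Tgfb1 (-0.97) and Cdh11 (0.63, in background in naive cells) differed most. In the endoderm list Dab2 alone passed (-0.63), in 1 of its 2 probe sets, and 17 of 18 genes did not (adjusted p = 0.73). Of the 18, 5 lay in background in both groups.

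Cell cycle genes were higher in naive cells in 6 of 17 cases and in primed cells in 2, with 9 not passing (adjusted p = 0.15). The cyclin genes Ccne2 (-1.04) and Ccnd2 (1.02) moved in opposite directions. Extracellular matrix genes were higher in naive cells in 4 of 12 cases and in primed cells in 1, with 7 not passing (adjusted p = 0.14), led by the basement membrane collagens Col4a2 (-0.42) and Col4a1 (-0.39). Genes of glycolysis were higher in primed cells in 4 of 16 cases and in naive cells in 1, with 11 not passing (adjusted p = 0.64). Pfkm (0.82) and Aldoc (0.56) led them. Their median was -0.05 while their mean was 0.08 and the test pointed to primed cells. Respiratory chain genes were higher in primed cells in 4 of 20 cases and in naive cells in 1, with 15 not passing (adjusted p = 0.53), among them Sdhb (0.38) and Ndufs3 (-0.32). The p53 targets gave 2 up, 2 down and 8 not passing of 12 (adjusted p = 0.55), with Perp at -0.78 and Sesn2 at 0.37. Genes of the 2-cell-like state were higher in naive cells in 3 of 10 cases and in primed cells in 0, with 7 not passing (adjusted p = 0.32), led by Eif1a (-0.63). In this list 6 of the 10 genes lay in background in both groups, among them Tcstv3 (-0.16), which passed. Adjusted over the list alone, the counts of these 12 lists were the same except for 4 rises among mesenchymal transition genes, 3 among respiratory chain genes and 2 falls among 2-cell-like genes.

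In all, 11 lists were higher in naive and 2 in primed cells with camera's preset correlation, and 0 and 0 with an estimated correlation, where 3 lists had an unadjusted p under 0.05. Some lists share members, such as Klf4 in the naive and LIF lists and Myc in the LIF and FGF lists. The lists are therefore not independent results. The fry test, which asks whether a list's genes move on balance in a direction without comparing them with other genes, called 18 lists in naive and 3 in primed cells. After removal of dim genes the naive pluripotency (adjusted p = 0.61), imprinted (0.060), Nodal (0.060), FGF (0.086), epithelial (0.091), interferon (0.091), fibroblast (0.11) and Wnt (0.15) lists no longer passed. Without genes in background on all arrays, chosen after the data were seen, the naive pluripotency, FGF, epithelial, interferon, fibroblast and Wnt lists each had an adjusted p of 0.059.

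Sex-linked genes were read gene by gene. Xist, the RNA that silences an X chromosome in female cells, lay in background in both groups (5.73 ± 0.08 and 5.69 ± 0.08, SD, n = 3). The Y-linked genes Eif2s3y (10.24 ± 0.07 and 10.68 ± 0.04) and Uty (9.58 ± 0.04 and 10.22 ± 0.03) were well above background in both groups and higher in primed cells. Kdm5d, also Y-linked, was in background in naive cells at 5.81 ± 0.16 and at 9.06 ± 0.02 in primed cells (SD, n = 3).

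Genes of chromosome 14 had the highest median difference of the 20 chromosomes tested, 0.17 over 339 expressed genes. With an estimated correlation, 0 of 20 chromosomes passed in camera, and 0 had an unadjusted p under 0.05. With the preset correlation chromosome 14 passed (adjusted p = 0.00091). A scan of gene order, chosen after the data were seen, placed the rise in a run of 129 expressed genes from Shisa2 to Tmtc4, the last gene scanned on the chromosome in assembly GRCm38.p6. The median difference in this run was 0.52, and 93.0% of its genes were higher in primed cells, against a median of -0.05 over the other 210 genes of the chromosome. The permutation p was 0.001, the smallest that 1000 permutations of gene positions can give, with neighbouring genes taken as independent. Among the genes named above, Sox21 of the neuroectoderm list lies in this run, as do Zic2 (0.64) and Zic5 (0.76) of the primed list. Klf5, in the naive list, lies there too and was lower in primed cells (-0.58).

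**Figure D3:**
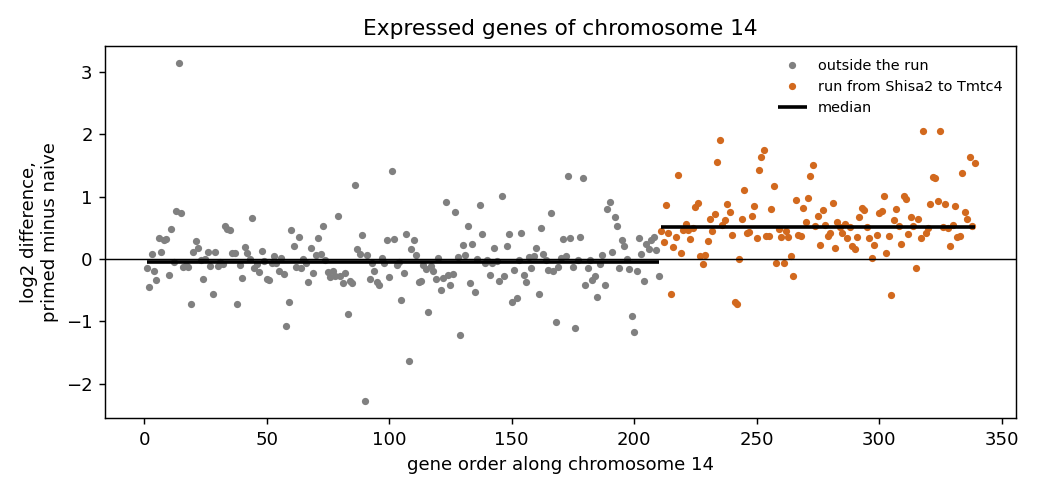
Log2 difference (primed minus naive) of each expressed gene of chromosome 14 against its rank in gene order, with the run from Shisa2 to Tmtc4 in orange and black lines at the medians. The run's median is 0.52 and that of the other genes is -0.05.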

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

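Removing the chromosome 14 run and removing genes in background on all arrays were chosen after the data were seen. Under every alternative tried, no call of a named gene or list was reversed. The genes higher in primed numbered 3926 to 4169 and the genes higher in naive 4007 to 4455 without each array in turn, with 2 and 11 lists and 0 chromosomes each time. At least 2-fold, the counts were 340 and 367, fewer by construction. Lists higher in naive cells numbered 3 without dim genes, 5 without genes in background on all arrays and 18 with fry. With an estimated correlation 0 lists passed in either direction. The preset correlation gave 1 chromosome. The cause of the lower counts with an estimated correlation, without dim genes or without background genes was not tested. The share of calls higher in primed cells, 49.0%, became 52.4% with median-centred arrays and 55.0% after quantile normalization again, so which group has more calls depends on the scaling. For named genes under alternatives, 1589 calls were the same, 14 were lost and 8 gained, among them Tcstv3, Ldha, Klf4, Gata4, Hhex and Arg2. Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at -0.11, 0.00 and -0.02. With the replicate block 8516 genes passed, 8413 of them shared with the 8876 of the unblocked fit, and the counts were 4172 and 4344. Dim signal is a limit: 616 genes past the threshold lay in background in both groups, and 59 of 1194 receptor genes (4.94%) passed.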

Other observations

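Tests of normalization, exchanged labels, feeder cells, culture state, medium and origin, and Dlk1, and the Hox, retinoid and microRNA groups were chosen after the results were seen, and small RNA genes of the chromosome 12 run were sorted again by RefSeq biotype after a result was seen. Among Hox genes, which pattern the body axis, 14 of 37 measured were higher in primed cells, 0 were higher in naive cells and 23 did not pass. Of the 14, Hoxb13, Hoxc4 and Hoxc6 lay in background in both groups and Hoxa3, Hoxa5, Hoxa9 and Hoxc5 in naive cells. No list test was run on the Hox, retinoid or microRNA genes. Hoxa2 went from 7.08 ± 0.21 to 9.23 ± 0.16 and Hoxa5 from 6.74 ± 0.06 to 8.74 ± 0.14 (SD, n = 3), and Hoxc5 rose by 0.97. Genes of retinoid signalling were higher in primed cells in 9 of 16 cases and in naive cells in 2, with 5 not passing. They include the receptor gene Rarb (3.15), the retinoic acid binding protein genes Crabp1 (2.84) and Crabp2 (2.24) and Cyp26a1 (1.04), which encodes an enzyme that degrades retinoic acid, while the receptor gene Rxrg, in background in primed cells, differed by -1.20.

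The microRNA cluster Mir302a to Mir302d with Mir367, abundant in pluripotent cells, was higher in naive cells for 5 of 5 genes, with differences from -1.71 for Mir302b to -2.23 for Mir367. A run of 242 expressed genes on chromosome 2, from Ovol2 to Polr3k, the last gene scanned, had a median of 0.16 with 73.6% of genes higher in primed cells (permutation p = 0.001, the smallest possible).

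The run on distal chromosome 14 lay at 0.52 in the median, near the 0.585 that 3 copies over 2 would give in the absence of compression. In the same way, 2 copies over 1 would give 1. Expression-matched lists from other chromosomes, 10000 in number, reached a median of 0.13 at most. This argues against an effect of normalization or intensity shared by genes of like expression. The run was picked for its shift, so these lists do not measure how often such a run arises by chance. A difference in copy number of the segment may account for the run, and which group would be altered was not tested. Of the segment genes that the scan did not use, 60 lay in background in both groups, where differences are compressed, and had a median of 0.02. The other 62 had a median of 0.14 (95% bootstrap interval 0.08 to 0.26), above the 0.02 of like genes elsewhere. By sign 51 of the 62 were higher in primed cells. Past the threshold, 28 were higher in primed cells and 4 in naive cells. The rise thus extended to segment genes that the scan did not use, which does not give its cause. The median of these 62 fell between the 0.2 predicted with a copy number difference and the 0.1 predicted without. The test therefore left a copy number difference open. Regulation by culture state cannot be told apart from it, since each group is a single culture condition, and the lowest of 9 pairs of arrays still gave 0.50.

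Genes of the naive and primed states moved both ways. Dilution by feeder cells as the whole cause is argued against by the pattern itself, since it would move naive-state genes to the same side. Of these genes, 6 were higher in primed and 14 higher in naive cells, and no separate test was made. A share of fibroblasts in a group stays open, because fibroblast genes (median -0.21) and core pluripotency genes (median -0.48) were both higher in naive cells and state differences could mask a dilution. Exchanged group labels were not excluded. Targets and components of LIF and STAT3 signalling (median -0.41) were higher in the cells labelled naive. However, FGF and ERK targets (median -0.22) and Fgf5 (-1.71) were too. Esrrb (2.98) and Nr0b1 (2.29) were higher in the cells labelled primed. Medium and origin of the line, either of which could account for the 14 and 6 genes, cannot be told apart if the origins differ as the titles say.

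On chromosome 12, a run of 26 expressed genes from Dlk1 to Mir369, the imprinted Dlk1 and Meg3 cluster, had a median of -1.30, and 26 of 26 genes were past the threshold and lower in primed cells. Of the 26, 23 are small RNA genes of this 1 cluster, so the genes are not independent observations. Silencing of the maternally expressed transcripts alone would not lower the paternally expressed Dlk1 and Rtl1, and both were lower in primed cells. Dlk1 (-1.59) is an end of the run, which was picked for such genes, so its value cannot decide. Rtl1 (-0.55), which the scan did not use, argues against this cause, as a single gene. The difference was not confined to small RNA genes, since the other 3 members, Dlk1, Meg3 (-0.47) and Rian (-1.61), had a median of -1.59. The scan picked the run for genes lower in primed cells. These 3 therefore cannot decide whether dim probe sets account for the differences of the small RNA genes. The run may be part of a wider difference at imprinted genes: the 11 listed outside it had a median size of difference of 1.20, at percentile 100 of 10000 expression-matched lists, whose 95th percentile was 0.36. Whether this came with culture or with the lines was not tested.

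The 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. In 1 of 10 splits, the real one, 8876 genes passed, and the highest of the others gave 0. For lists the real split gave 13 (1 of 10) and the highest other 5. Each other split mixes naive and primed arrays, so the real difference becomes spread within its groups. Low counts there were built in, and they cannot tell whether the real counts arose by chance. The split test for the runs was set before the splits were run, though the gene order scan itself was chosen after the data were seen. The highest run statistic of the scan was 14.18 for the real split and 14.25 for the highest other, so 2 of 10 splits were as large. That statistic uses ranks, which keep a shared part of the group difference in every split and lose its size.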
